A study of Homo sapiens with 6 samples.

How the data were processed

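ATAC-seq libraries were made from primary myometrial cells of 3 donors, each transduced with an empty lentiviral vector (control) or a vector for V5-tagged HMGA2, which gave 3 control and 3 HMGA2 libraries. Per the labels' protocols, cells were transduced for 18 h with 6 µg/ml polybrene and selected in 2 µg/ml puromycin. About 12500 nuclei per library were tagmented for 30 min at 37 °C, libraries were amplified for 9 PCR cycles, and fragments were sequenced from both ends with 42 bp reads. Reads were handled with FastQC, Bowtie2 2.2.6 and MACS2 2.2.6 on the hg38 build, per the submitters' processing notes. Whether read ends were shifted for the transposase offset, and how duplicates and mitochondrial reads were treated, is not given in the sources used here.

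Each deposited file is a MACS2 peak list of a single library, so peaks were called per library and not on pooled samples. The deposited lists give for each peak a fold enrichment over background, the −log10 of its p-value, the −log10 of its q-value, an integer score and the position of the summit. In the deposited lists every fold was a whole multiple of a step that is constant within a library (all values within a tolerance of 0.01). From that step the background pileup of each library was computed. The Poisson tail of summit pileup over this background returned the deposited −log10 p to within 1.54e-05 where it was under 250. Within a list the deposited fold and −log10 p therefore rank peaks alike, and the planned ranking by fold could give no other result. Folds, scores and −log10 p were used only to describe, rank and filter peaks within a list. The total number of reads per library is not given in the sources used here, and the background pileup served as the measure of relative depth.

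Rows on chromosomes 1 to 22 and X were kept. Rows on other sequences made up 832 to 1262 per list, and no 2 rows of a list had the same interval. Because list length moves with depth, regions and loci were compared on matched lists, the 100000 peaks of each library with the highest −log10 p, with ties in random order. A peak outside this list is a lower-ranked peak or no peak, and a region missing from a matched list is not thereby closed. Peaks of the 6 matched lists that overlapped by at least 1 bp were merged into regions. A gained region had a peak in all 3 HMGA2 lists and in no control list, a lost region the opposite. Positions were described with RefSeq genes of GRCh38.p14, the same build as the files, of which 37724 genes were used (19821 protein-coding) and 426 listed with scaffold coordinates were left out. The annotation used here held gene bodies without strand, exons or sequence. For this reason the planned promoter class became the interval within 1 kb of either end of a protein-coding gene, and the remaining classes were the gene body and the space outside protein-coding genes. Exon and intron shares, GC content, motifs and windows of 50 kb around start sites, all planned, were not run.

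Single values per library were compared with a two-sided exact permutation test of 3 against 3, whose smallest p is 0.1, and within donors with an exact sign-flip test, whose smallest p is 0.25. Peaks were counted in each gene locus (gene body and 5 kb to each side), and log2(peaks + 1) was tested with limma 3.58.1 (intensity trend, no block) under R 4.3.3 for protein-coding and lncRNA genes with a mean of at least 2 peaks, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes on this scale understate the change of loci with few peaks. A total of 19 gene lists were tested with camera (correlation preset to 0.01). Other steps ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Tests over regions used 100000 resamples. Regions and genes are not replicates, and such p-values describe the sets and not the donors.

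The steps were tested on simulated data. All 1643 gained and 1713 lost simulated regions were found. For the HMGA2 against control comparison, peak counts with no change were simulated 10 times, and the locus test called 157 to 188 of about 15921 loci. With changed loci added, 69.4% of the calls were false, nearly all of them at loci whose count was identical in all libraries of each group. It recovered 11.2% of 1.5-fold, 26.5% of 2-fold, 63.5% of 3-fold and 79.9% of 4-fold changes. With a mean of at least 5 peaks there were 0 calls with no change, 1.54% of calls were false, and 24.5%, 64.6%, 93.5% and 98.5% of these changes were recovered. For this reason the counts with a mean of at least 5 peaks, and with identical loci left out, stand beside the main ones. Camera called 0 lists in 10 simulations with no change and found a 1.5-fold changed list in 10 of 10, with 1 false list beside it. The simulated loci were drawn independently of each other, so these runs do not test camera on lists whose members are correlated. In the data the estimated correlation of the neuronal list was 0.0758, above the preset 0.01.

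The groups, tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. That rule takes HMGA2 first, then the 10 largest increases and 10 largest decreases among called protein-coding loci with the same direction in all 3 donors. It adds the 10 genes with the most gained and the 10 with the most lost regions, the 10 highest ranked genes with a gene-end peak in 1 group only for each direction, and up to 4 members of each list by lowest p, of which at least 2 and every called member are given. One gene-end loss that the rule takes is not reported here. The lists cover extracellular matrix, smooth muscle contraction, the axis of HMGA2, let-7 and IGF, TGF-beta and BMP signalling, WNT signalling, steroid hormone response, AP-1 factors, HOX genes, cell cycle, senescence and secretory factors, interferon response, mesenchymal transition factors, neuronal and synaptic genes, housekeeping genes, and markers of fibroblasts, pericytes, endothelium, epithelium and immune cells. Libraries with the same donor number come from the same donor, so the numbers pair them. Deviations from the group means correlated at 0.176, 0.134 and 0.222 within the 3 donors and at −0.00578 or less between donors. Alternatives were stricter thresholds, other list lengths, other definitions of a region, of absence and of a locus, other pseudocounts and filters, donor as a block, and each library or donor left out.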

Results

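Accessible chromatin was mapped by ATAC-seq, in which a transposase cuts and tags open DNA, in cells cultured from the myometrium, the muscle layer of the uterus. Cells of 3 donors were each transduced with an empty vector (control, n = 3) or with V5-tagged HMGA2 (n = 3), a chromatin protein that binds A/T-rich DNA and is overexpressed in a subset of uterine leiomyomas. The comparison asks which accessible regions differ when HMGA2 is overexpressed in otherwise normal myometrial cells. The control libraries of donors 1, 2 and 3 held 329341, 316356 and 305265 peaks, and the HMGA2 libraries held 434738, 408952 and 372085. The background pileup, the only measure of depth in the lists, averaged 2.28 ± 0.134 in control and 2.53 ± 0.127 in HMGA2 libraries (SD, n = 3).

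The endogenous HMGA2 locus (hg38, chromosome 12, 65824460 to 65966291) was accessible in all 6 libraries. Among the 100000 highest peaks of each library it held 19, 17 and 22 peaks in the control and 17, 17 and 15 in the HMGA2 libraries of donors 1 to 3. For the means of 19.3 ± 2.52 and 16.3 ± 1.15 (SD, n = 3) the exact permutation test gave p = 0.3, and limma gave a log2 change of −0.23 ± 0.11 (SE, adjusted p = 0.301). With every deposited peak counted the locus held 73.7 ± 8.02 in control and 92.3 ± 13.8 in HMGA2 libraries (SD, n = 3; exact permutation p = 0.2), which is 2.33 ± 0.316 and 2.27 ± 0.188 of every 10000 peaks in a list (p = 0.8). The direction flipped with covered base pairs in place of peaks (0.04). Peaks at this locus do not measure expression from the vector, so they do not check the labels.

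HMGA2 libraries held more peaks than the control library of the same donor in each of the 3 donors. The mean was 405258 ± 31489 against 316987 ± 12050 (SD, n = 3), a ratio of 1.28, with ratios of 1.32, 1.29 and 1.22 in donors 1 to 3. Peaks covered 199.8 ± 22.3 Mb in HMGA2 and 160.3 ± 11.9 Mb in control libraries. The surplus lay among weak peaks. With a fold of at least 4, by the authors' own value for each peak, the ratio was 1.18. With a fold of at least 10 the means were 104985 ± 8190 and 106106 ± 9712, a ratio of 0.989, and the HMGA2 library held more in 2 of 3 donors. For all peaks the exact permutation test gave p = 0.1 and the exact sign-flip test within donors p = 0.25, each the smallest value its design allows. At a fold of at least 10 the exact permutation test gave p = 1.

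**Figure D1:**
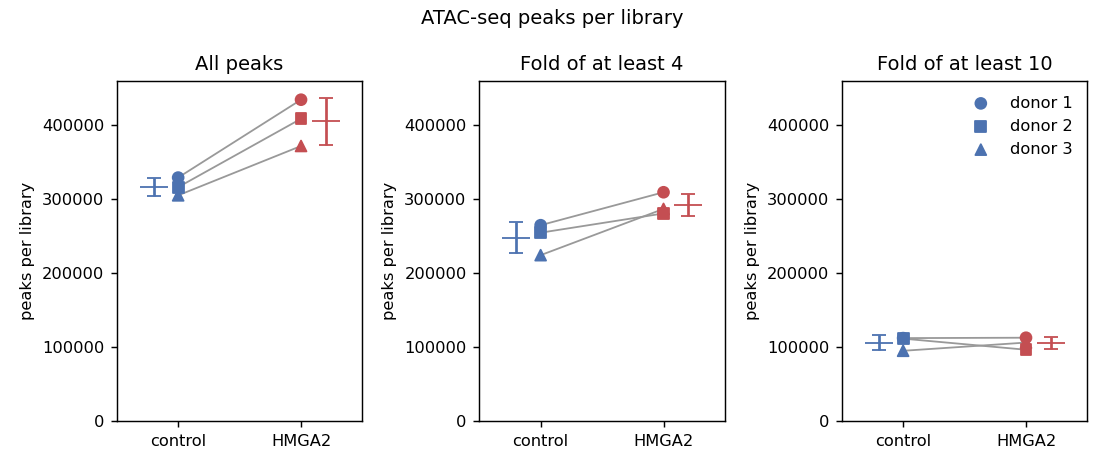
Number of peaks per library for all peaks, peaks with a fold of at least 4 and peaks with a fold of at least 10. Symbols are single libraries, grey lines join the libraries of a donor, and bars beside them give mean ± SD (n = 3); HMGA2 lies above control in all 3 donors for all peaks and in 2 of 3 at a fold of at least 10.

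HMGA2 was accompanied by gains and losses of regions that all 3 donors shared. Of 141344 regions, 60316 (42.7%) held a peak in all 6 matched lists, 6663 were gained (5.80 Mb) and 5244 were lost (4.14 Mb). The 9 other ways of splitting the 6 libraries into 3 and 3 gave at most 776 regions in a direction. Matched lists of the same group shared 70.4 to 80.1% of their regions, those of the same donor 62.6 to 66.6%, and lists of different donor and group 58.6 to 64.4%. The differences were mostly of rank and not of presence. Of the gained regions, 5078 (76.2%) overlapped a lower-ranked peak in every control library and 295 overlapped no deposited control peak. Of the lost regions, 4962 (94.6%) overlapped a deposited peak in every HMGA2 library and 32 in none. Deposited control lists were shorter than HMGA2 lists, so these counts are not alike for both directions. With lists cut to 300000 peaks, 340 gained regions overlapped no control peak and 92 lost regions overlapped no HMGA2 peak.

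**Figure D2:**
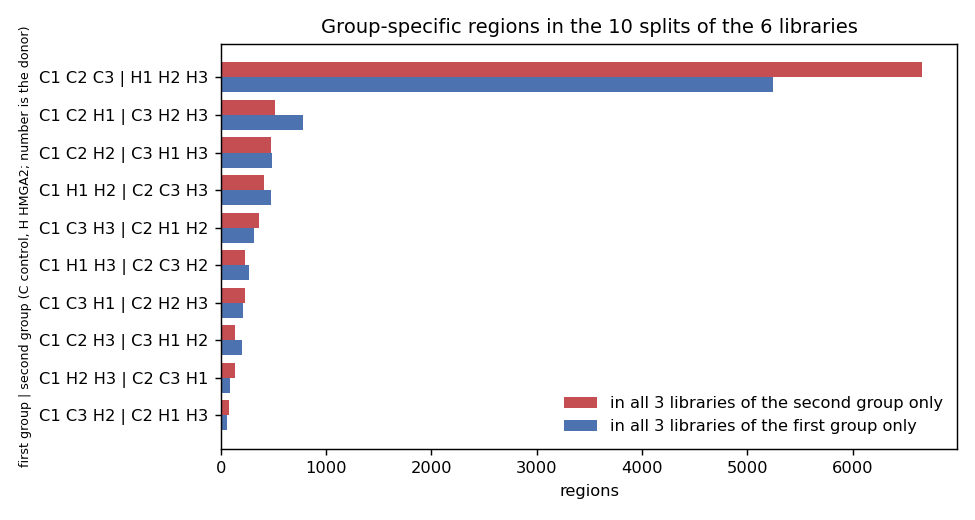
Regions found in all 3 libraries of a group and in no library of the opposite group, for each of the 10 splits of the 6 libraries (C control, H HMGA2, numbers are donors). The split into control and HMGA2 gives 6663 and 5244 regions, and no other bar passes 776.

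Gained regions lay mostly between genes, and lost regions mostly within them. Outside protein-coding genes lay 57.9% of gained, 32.0% of lost and 39.1% of shared regions. These shares were not computed for random positions, so they are relative to the other regions and not to the genome. Gene bodies held 39.2% of gained, 61.0% of lost and 41.1% of shared regions, and intervals within 1 kb of a gene end held 2.90%, 6.94% and 19.8%. Gained regions had a median of 5 protein-coding genes within 500 kb, lost regions 8, shared regions 7 and random positions 4. Each of these differences in share between gained and lost regions, and in mean gene number (6.92 against 10.5), gave p = 1e-05 in a permutation test over regions, the smallest value that 100000 resamples can give. Within single donors, 54.2 to 56.4% of the regions gained in that donor and 36.2 to 37.4% of those lost lay between genes.

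The same shift was seen over whole matched lists. Intergenic peaks made up 43.5% ± 0.0866 of HMGA2 and 39.7% ± 0.155 of control lists (SD, n = 3), gene bodies 42.5% ± 0.305 and 45.8% ± 0.102, and gene ends 14.0% ± 0.347 and 14.5% ± 0.190. Each share differed in the same direction in 3 of 3 donors, and each exact permutation test gave p = 0.1 (adjusted p = 0.1 over the 3 classes). Over all deposited peaks the differences were smaller: HMGA2 lists held 0.937 percentage points more intergenic peaks (exact p = 0.3), where matched lists held 3.76 points more. Among the 50000 highest peaks HMGA2 lists held 4.86 points more intergenic peaks. Gene ends there made up 19.6% ± 1.64 of HMGA2 and 22.4% ± 0.779 of control lists (SD, n = 3). The difference in gene bodies was smaller there (−2.02 points), and each exact permutation test gave p = 0.1.

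**Figure D3:**
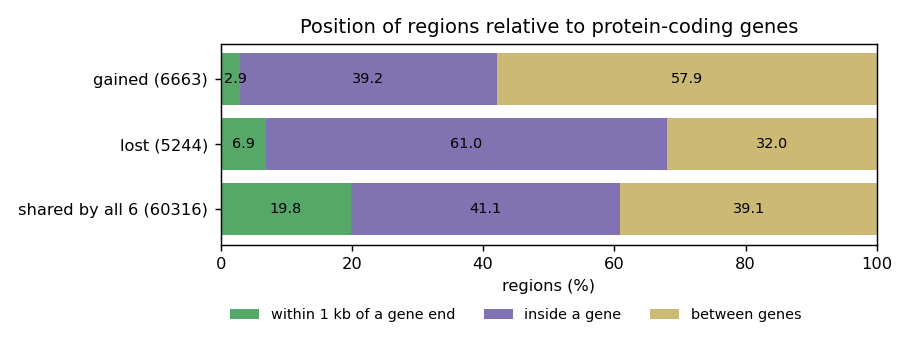
Share of gained, lost and shared regions, in percent, within 1 kb of an end of a protein-coding gene, inside such a gene, or between genes. Gained regions are 57.9% intergenic and lost regions 61.0% within gene bodies.

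The 10 genes with the most gained regions held 7 to 18 each. This ranking by number makes no allowance for gene length, so long genes have more room for regions. KAZN, which encodes a protein of the cornified envelope and desmosomes (chromosome 1, 13892824 to 15118043), held 18 gained regions and ASIC2, an acid-sensing sodium channel (chromosome 17, 33013087 to 34156768), held 14. MACROD2, a mono-ADP-ribosyl hydrolase, held 13, the fragile-site gene FHIT 11 and HPSE2, a heparanase homologue, 9. ALK, a receptor tyrosine kinase, GRIA1, a glutamate receptor subunit, NRG1, a ligand of ERBB receptors, and OPCML, a cell adhesion protein, held 8 each, and AGBL1 held 7. Peak numbers in the locus test rose at KAZN from 36.7 ± 0.577 to 64.3 ± 3.06 peaks (SD, n = 3; log2 change 0.79 ± 0.04 SE, adjusted p = 0.000488) and at ASIC2 from 19.7 ± 3.21 to 47.3 ± 4.93 (1.23 ± 0.15, adjusted p = 0.0180). They also rose at OPCML (1.16), AGBL1 (0.97), GRIA1 (0.89), HPSE2 (0.86), MACROD2 (0.59) and ALK (0.50). FHIT (0.50, adjusted p = 0.0862) and NRG1 (0.34, adjusted p = 0.107) did not pass. With donor as a block, KAZN (adjusted p = 0.0260) and MACROD2 (0.0242) kept their calls, while the other called genes had adjusted p from 0.0535 (ASIC2) to 0.153 (HPSE2). KAZN kept its call with any 1 library left out and the other 7 were called in only 1 or 2 of these 6 runs (adjusted p up to 0.139 for HPSE2). Over all deposited peaks the change was 0.01 at MACROD2 and 0.00 at ALK.

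The 10 genes with the most lost regions held 5 to 8 each, also with no allowance for gene length. Ties were taken in order of symbol, so CDH11, with 5 lost regions as at ADAM12, is not among them. VPS13D, a lipid transfer protein, held 8, the focal adhesion gene LPP 7, and ADAMTSL1, BICC1, GSE1, NOTCH2NLB, PTPRG, RBFOX2 and RBMS1 held 6 each, with 5 at the metalloprotease gene ADAM12. Gained regions also lay at LPP (6), ADAMTSL1 (3) and PTPRG (2), and at GSE1, RBFOX2, RBMS1 and ADAM12 (1 each), so gains and losses nearly balanced at LPP. BICC1, an RNA-binding protein, fell from 21.3 ± 0.577 to 12.3 ± 1.53 peaks (SD, n = 3; log2 change −0.75 ± 0.09 SE, adjusted p = 0.0181). NOTCH2NLB fell by 0.84 on the log2 scale (adjusted p = 0.0454), but it has near-identical paralogs between which reads can be split. Of these genes, the other 8 did not pass in the locus test. Neither call held with donor as a block (adjusted p = 0.113 and 0.150) or with most single libraries left out (up to 0.128), while GSE1 passed with the block (0.0451). Of the 10 genes, NOTCH2NLB (0.12), LPP (0.39), RBFOX2 (0.41), RBMS1 (0.37) and ADAM12 (0.15) changed direction over all deposited peaks.

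In the locus test, 372 of 16956 loci had more and 594 had fewer peaks with HMGA2. The largest called increase was at SHISA9 (chromosome 16, 12901598 to 13563017), an auxiliary subunit of AMPA receptors, with 0 matched peaks in every control and 7, 10 and 6 in the HMGA2 libraries (adjusted p = 0.000968). ANO2, a calcium-activated chloride channel (chromosome 12, 5562655 to 5946232), rose from 2 ± 1 to 14.7 ± 4.16 peaks (SD, n = 3; log2 change 2.40 ± 0.35 SE, adjusted p = 0.0352). ACSM5, a mitochondrial acyl-CoA synthetase, rose by 2.39 (adjusted p = 0.0311) and CTNND2, a delta-catenin of cell junctions, by 2.30 (0.0431). RBFOX1, a neuronal splicing factor, rose by 1.64, ROBO2, an axon guidance receptor, by 1.58, and MAPK4, an atypical MAP kinase, by 1.41. TMEM178B rose by 1.39, and GJB7, a connexin, and TNR, a matrix glycoprotein of the nervous system, by 1.38 each. All 10 kept their direction over all deposited peaks. There the log2 change was larger at SHISA9 (3.44) and RBFOX1 (4.05) and smaller at the other 8, among them ROBO2 (0.36), TNR (0.64) and CTNND2 (0.71). Of the 10 genes, 3 of 3 testable with a mean of at least 5 peaks (ANO2, TMEM178B and TNR) kept their call. SHISA9 and MAPK4 kept their call with any 1 library left out, while the other 8 were called in only 1 or 2 of these 6 runs (adjusted p up to 0.137). At SHISA9, RBFOX1, MAPK4 and GJB7 all control libraries had the same count, of 0 to 2 peaks. With donor as a block CTNND2, RBFOX1, ROBO2, GJB7 and TNR no longer passed (adjusted p from 0.0763 for RBFOX1 to 0.173 for CTNND2), and over all alternatives adjusted p for the 10 genes ranged from 8.26e-06 to 1.

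The largest decrease was at RRAGD (chromosome 6, 89364616 to 89412273), a Rag GTPase of the mTORC1 pathway, with 5, 4 and 5 matched peaks in control and 0 in every HMGA2 library (adjusted p = 9.51e-05). SPOP, a substrate adaptor of a cullin ubiquitin ligase, fell from 9 ± 3 to 2 ± 0 peaks (SD, n = 3; log2 change −1.69 ± 0.24 SE, adjusted p = 0.0326). PDK2, a pyruvate dehydrogenase kinase, fell by 1.61 (adjusted p = 0.0140). PRRT4 (−1.41), NBEAL1 and SLTM (−1.39 each), ELF1, an ETS transcription factor (−1.36), PSME4, a proteasome activator (−1.35), and RIC1 and TMEM135 (−1.34 each) also fell. Over all deposited peaks 5 of the 10 turned (log2 change of 0.02 for SPOP, 0.24 for NBEAL1, 0.15 for SLTM, 0.58 for PSME4 and 0.73 for RIC1). The other 5 kept their direction at much smaller changes (−0.60 for RRAGD, −0.08 for PDK2, −0.21 for PRRT4, −0.12 for ELF1 and −0.41 for TMEM135). With donor as a block RRAGD, PRRT4 and PSME4 kept their call and the other 7 had adjusted p from 0.0508 (RIC1) to 0.138 (TMEM135), over all alternatives 8.23e-12 to 1. RRAGD, PRRT4, ELF1, PSME4 and RIC1 kept it with any 1 library left out, and the other 5 were called in only 1 to 3 of these 6 runs (adjusted p up to 0.125). At RRAGD, SPOP, PRRT4, PSME4 and RIC1 all HMGA2 libraries had the same count, of 0 to 2 peaks. At PDK2, NBEAL1 and SLTM all control libraries had the same count, of 5 or 6 peaks. Only SPOP and ELF1 were testable with a mean of at least 5 peaks, and both kept their call.

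Of all calls in the locus test, 498 were at loci with identical counts in the libraries of each group, a kind that the simulations showed to be called without any change. With another random order of tied peaks ANO2 (adjusted p = 0.0716), RBFOX1 (0.143), SPOP (0.0866), ALK (0.0568), NOTCH2NLB (0.0829), COL5A1 (0.0586), ROR1 (0.0552) and SDHA (0.287) no longer passed. Without the loci of identical counts 172 had more and 296 had fewer peaks, and with a mean of at least 5 peaks 118 and 229 of 4903, of which 75 and 158 were among the main calls. The balance of directions depended on the scaling: 409 more and 77 fewer with each library centred on its median (a shift of 0.21), 537 and 318 with covered base pairs, and 2519 and 2282 over all deposited peaks scaled to the same total. An exact binomial test on summed peaks called only KAZN, ASIC2, ANO2 and SHISA9, all with more peaks, and 0 with fewer (259 loci at an unadjusted p under 0.05). Counts within groups varied less than this test assumes (variance over mean of 0.153), so the test is conservative here.

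**Figure D4:**
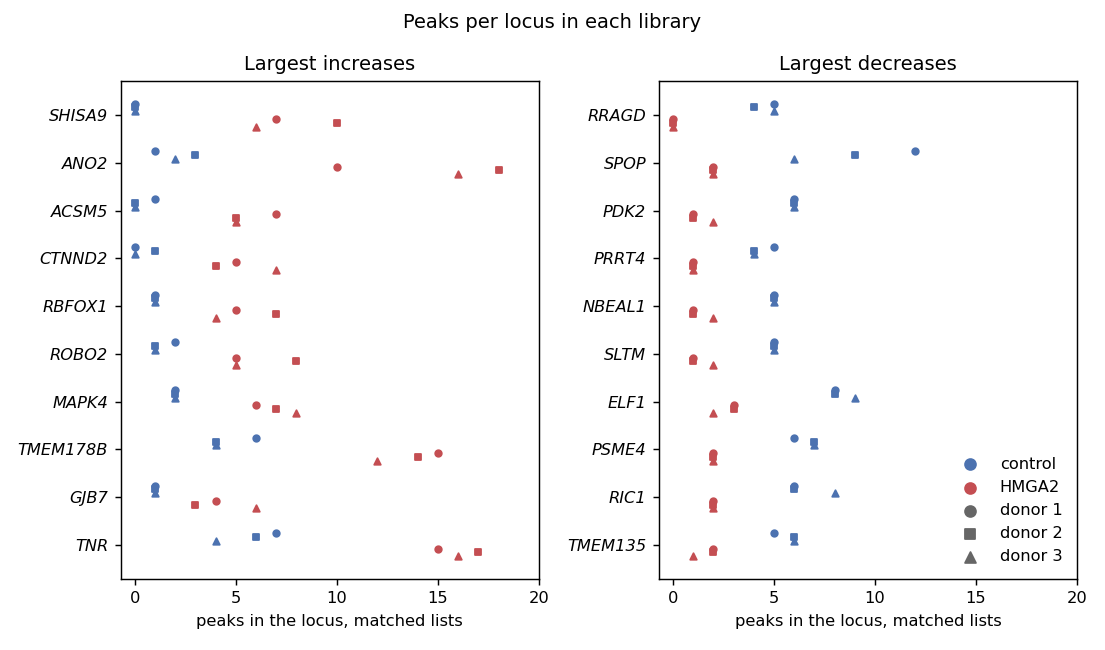
Peaks per locus in the matched list of each library at the 10 loci with the largest increase and the 10 with the largest decrease. Control libraries are blue and HMGA2 libraries red, with a symbol for each donor; at SHISA9 all controls and at RRAGD all HMGA2 libraries are at 0.

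Few of the differences lay at gene ends. A peak within 1 kb of an end was gained at 80 protein-coding genes and lost at 198, and at 69 and 190 of these genes a gained or lost region lay there. Among the highest ranked gains with a gained region were CYP4F12, a cytochrome P450, LOC124905938, SYT9, a synaptotagmin of vesicle release, and SERPINA9, a serpin protease inhibitor. The other highest ranked gains, at PHLDB2, ZNF621, ACKR2, ZNF19, HHAT and SLC1A3, had no gained region within 1 kb of an end. Among the highest ranked losses with a lost region were PDE4A, a cyclic AMP phosphodiesterase, NOL10, DRD4, a dopamine receptor, DLX4, a homeobox factor, LINGO2 and SYNGR2. Other highly ranked losses, at FAM120B, ARHGAP4 and OSCAR, had no lost region there. At only 6 genes with a gain, PHLDB2, ZNF621 and ACKR2 among them, and 3 with a loss, among them OSCAR, did no deposited peak of the opposite group lie within 1 kb of an end. The locus of ZNF621 held 1 matched peak and that of OSCAR 2 in every library of both groups. The number of matched peaks in these loci therefore did not differ.

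Among the gene lists, only that of neuronal and synaptic genes passed. Of 24 measured members 18 were higher and 6 lower in HMGA2, with a median log2 change of 0.22 (camera adjusted p = 0.0212; adjusted p = 0.488 with an estimated correlation). RBFOX1 (1.64 ± 0.19 SE, adjusted p = 0.0139) and GRIA1 (0.89 ± 0.12, adjusted p = 0.0224) passed, 2 members both over all genes and adjusted over the list alone. GRID1 (1.12, adjusted p = 0.149) and PTPRD (0.31, adjusted p = 0.128; −0.20 over all deposited peaks) did not. The call held with donor as a block (adjusted p = 0.0124) and was lost without control donor 2 (0.0668), without control donor 3 (0.182) and over all deposited peaks (0.732), within a range of 0.00263 to 0.732 over all alternatives. Neither called member passed with the block (adjusted p = 0.0763 and 0.0760).

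Matrix and mesenchymal lists leaned the opposite way without passing in the main test. In the extracellular matrix list 31 of 40 loci were lower and 8 higher (median −0.20, camera adjusted p = 0.0757). COL3A1, the fibrillar collagen III gene, fell from 10.7 ± 0.577 to 5.67 ± 0.577 peaks (SD, n = 3; log2 change −0.81 ± 0.08 SE, adjusted p = 0.00859), and COL5A1 fell by 0.30 (0.0159), 2 members also adjusted over the list alone. COL1A1, a chain of collagen I, was at 0.85 (adjusted p = 0.0838) and LOXL1, a lysyl oxidase, at −0.25 (0.0906). In the list of mesenchymal transition factors 14 of 19 loci were lower (median −0.20, adjusted p = 0.0757). The cadherin CDH11 fell by 1.22 (adjusted p = 0.0336) and WWTR1, the Hippo pathway coactivator TAZ, by 0.41 (0.0236), while YAP1 was at −0.55 (0.0584) and VIM at −0.52 (0.0672), and 5 members passed adjusted over the list alone. Over all deposited peaks CDH11 turned to 0.40 and YAP1 to 0.25, with covered base pairs COL1A1 to −0.09 and VIM to 0.68. By camera the matrix list passed over all deposited peaks (adjusted p = 0.00755), with a mean of at least 5 peaks (0.0342) and with gene bodies only (0.0445), and it did not with an estimated correlation (0.488), with donor as a block (0.0545) or with the 50000 highest peaks (0.636). CDH11 passed with donor as a block (adjusted p = 0.0451) and LOXL1 came to pass (0.0326), while COL3A1 (0.0832), COL5A1 (0.129) and WWTR1 (0.142) did not.

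Contractile genes did not pass as a list. Of 29 measured loci 19 were lower and 6 higher (median −0.14, camera adjusted p = 0.272). Vinculin (VCL) fell by 0.52 (adjusted p = 0.0180), caldesmon (CALD1) by 0.27 (0.0276) and TPM2, a tropomyosin, by 0.32 at identical counts within groups, 3 members also adjusted over the list alone. VCL no longer passed with donor as a block (adjusted p = 0.120). The directions of VCL (0.50 over all deposited peaks), CALD1 (0.33 with covered base pairs) and TPM2 (0.19 with the 50000 highest peaks) flipped. HOX genes were lower at 18 of 23 loci (median −0.21, camera adjusted p = 0.272), with 0 called by limma in either direction. HOXA11 was at −0.60 (adjusted p = 0.0832) and HOXA10 at −0.48 (0.0981), and both flipped with covered base pairs (0.09 and 0.17).

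The signalling lists did not pass. Camera's adjusted p was 0.296 for TGF-beta and BMP signalling, where the BMP receptor BMPR2 fell by 0.95 (adjusted p = 0.0176; 0.01 over all deposited peaks) and SMAD3 was at −0.22. It was 0.983 for WNT signalling, where TCF7L1 fell by 0.33 (adjusted p = 0.0241) and the receptor ROR1 rose by 0.43 (0.0470; −0.01 over all deposited peaks), and adjusted over the list alone 1 member rose and 2 fell. It was 0.849 for steroid hormone response, where HAND2, a progesterone-regulated factor, fell by 0.63 (adjusted p = 0.0431) and FOXO1 was at −0.65 (0.0832; 0.02 over all deposited peaks). It was 0.469 for the axis of HMGA2, let-7 and IGF, with PAPPA, a protease of IGF-binding proteins, at 0.42 (adjusted p = 0.0784) and IGF2BP2 at −0.35 (0.0752). With donor as a block both passed (0.0342 and 0.0153), but IGF2BP2 turned to 0.47 over all deposited peaks and 0.02 with covered base pairs, and PAPPA to −0.19 with the 50000 highest peaks. BMPR2, TCF7L1, ROR1 and HAND2 no longer passed with the block (adjusted p from 0.116 to 0.148). AP-1 factors gave 0.647, with MAF at 0.72 (adjusted p = 0.288; 0.0102 with donor as a block) and JUNB at −0.35, which flipped over all deposited peaks (0.21) and with covered base pairs (0.04).

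Lists of cell state and of other cell types did not pass either. Camera's adjusted p was 0.647 for the cell cycle, 0.296 for senescence and secretory factors, 0.272 for interferon response, 0.963 for fibroblast, 0.296 for pericyte, 0.737 for endothelial, 0.436 for epithelial and 0.794 for immune markers, and 0.272 for housekeeping genes. Among cell cycle genes MCM2 was at 0.52 (adjusted p = 0.0672) and RB1 at −0.63, and among senescence genes CCL2 was at 0.46 and CDKN1A at 0.67 (0.288). Among fibroblast markers CD34 rose by 0.63 (adjusted p = 0.0431) and MFAP5 fell by 0.42, and among pericyte markers STEAP4 rose by 1.00 and ABCC9 was at −0.50 (0.0865). The interferon-induced IFIT3 rose by 0.32, with MX1 at 0.55 (0.143), and the housekeeping genes TFRC and SDHA fell by 0.42 and 0.26. MFAP5, STEAP4, IFIT3, TFRC and SDHA had identical counts within each group. PECAM1 (0.34), FLT1 (0.29), KRT18 (0.38), GRHL2 (0.65), CD68 (−0.55) and PTPRC (−0.21) did not pass. CD34 no longer passed with donor as a block (adjusted p = 0.130). Of the called list members whose counts varied within groups, COL3A1 kept its call with any 1 library left out. The others were called in 0 (ROR1) to 5 (COL5A1) of these 6 runs (adjusted p up to 0.145 for ROR1). Over all deposited peaks MCM2, CDKN1A, IFIT3, MX1, KRT18, GRHL2, TFRC and SDHA flipped. The median, mean and test differed in sign for the WNT (median −0.02, mean −0.07, tested up) and endothelial lists (−0.04, −0.02, tested up), and the mean and test for the cell cycle (−0.04) and the HMGA2 axis (0.00, mean −0.00223).

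**Figure D5:**
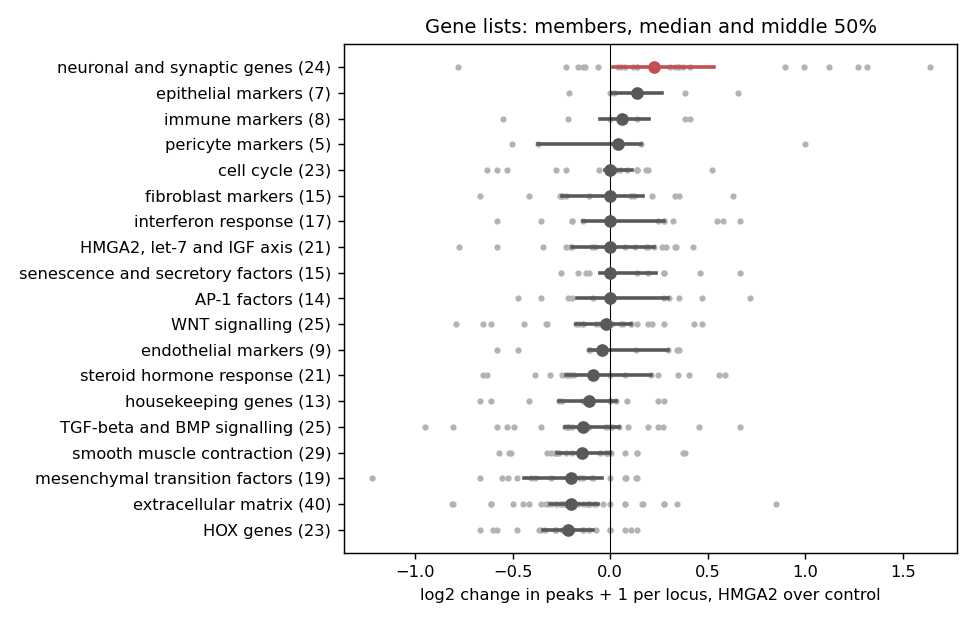
Log2 change in peaks + 1 per locus, HMGA2 over control, for the measured members of each gene list (small grey points), with the list median (large point) and the middle 50% of members (line). The list of neuronal and synaptic genes, in red, is the only list past camera's threshold (adjusted p = 0.0212), and with an estimated correlation it does not pass (0.488).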

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

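The thresholds of a fold of at least 10, thinned pileups, other tie orders, no chromosome X, gene body loci, the exact binomial test, loci with identical counts left out and the list tests with a mean of at least 5 peaks or a library left out were chosen after the results were seen. The direction of the peak number held in 8 of 9 alternatives (ratio 1.18 to 1.31) and turned at a fold of at least 10 (0.989). The class shares kept their direction in all alternatives run. Gained and lost regions numbered 3053 and 2366 with the 50000 highest peaks, 25443 and 16291 with lists as long as the shortest, 47126 and 10111 with all deposited peaks, and 295 and 32 with absence judged against every deposited peak. With a donor left out they numbered 9000 to 11144 and 7410 to 10632, since fewer libraries had to share a region. With 50% of a region covered, windows around summits, another tie order or no chromosome X they stayed within 1.5 times (6429 to 8391 and 5158 to 5700). Loci with more and fewer peaks numbered 1138 and 1368 with no filter, 118 and 229 with a mean of at least 5 peaks, 151 and 259 with the 50000 highest peaks (19 and 19 among the main calls), 2519 and 2282 over all deposited peaks (72 and 106), 537 and 318 with covered base pairs, 409 and 77 with median centring, 266 and 395 with gene bodies only, 172 and 296 without loci of identical counts, and 4 and 0 in the exact binomial test. Filters changed these counts by the loci tested, and for the rest the cause was not tested. With each library left out they numbered 386 to 514 and 560 to 772. With donor as a block they numbered 342 and 532, of which 236 and 353 were among the main calls. The block gave a ratio of peak numbers of 1.28 and 1 gene list. Among the genes named here it changed the calls printed in the results and that of PDE4A (limma adjusted p = 0.0494 in the main test, 0.169 with the block). Over all deposited peaks 30.9% of the loci called with more and 30.0% of those called with fewer peaks turned, and 7 and 32 of them were called the opposite way. In those lists the log2 changes of SPOP (0.021), NBEAL1 (0.24), SLTM (0.15), PSME4 (0.58), RIC1 (0.73), LPP (0.39), NOTCH2NLB (0.12), RBFOX2 (0.41), RBMS1 (0.37), ADAM12 (0.15), VCL (0.50), IGF2BP2 (0.47), BMPR2 (0.014), ROR1 (−0.0055), FOXO1 (0.016), JUNB (0.21), MCM2 (−0.31), CDKN1A (−0.69), IFIT3 (−0.12), MX1 (−0.21), CDH11 (0.40), YAP1 (0.25), PTPRD (−0.20), KRT18 (−0.25), GRHL2 (−0.11), TFRC (0.55) and SDHA (0.15) reversed. Covered base pairs reversed HMGA2 (0.041), LPP (0.18), RBMS1 (0.027), COL1A1 (−0.092), VIM (0.68), CALD1 (0.33), IGF2BP2 (0.020), JUNB (0.038), HOXA11 (0.092) and HOXA10 (0.17), the 50000 highest peaks TPM2 (0.19) and PAPPA (−0.19), and median centring, which adds 0.21 to the change of every locus, LPP (0.096), GSE1 (0.015) and ADAM12 (0.095). The cause of the other reversals was not tested. The number of gene lists past the threshold was 0 with an estimated correlation, 9 with fry, which does not compare a list with other genes, 2 with a mean of at least 5 peaks, 2 with gene bodies only, and 0 to 1 with a library left out (0 without control donor 2 or 3). Over the genes named with a log2 change, those with the most changed regions and the neuronal, matrix and mesenchymal lists, 42 values reversed as given, 797 kept their direction and side of the threshold, 310 fell below it, 36 passed it and 70 counts of regions moved by more than 1.5 times. Ranking by fold gave the same ranking, and windows around start sites, GC content and motifs were not run.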

Other observations

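The tests at a fold of at least 10 and of randomly placed gains were chosen after the results were seen, as were the loci singled out here. The comparison of regions with other splits was planned, but its criterion was written after the results were seen.

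Gains and losses were uneven over chromosomes. The mean share of matched peaks on chromosome 20 was 6.16% higher with HMGA2 and that on chromosome 8 was 2.84% higher, each in 3 of 3 donors. Shares were lower in 3 of 3 donors on chromosome 19 (−7.70%), chromosome 17 (−6.83%) and chromosome 13 (−4.32%). Over 22 autosomes the log2 ratio followed the number of genes per Mb with Pearson's r of −0.535 (permutation p = 0.0126) and Spearman's rho of −0.220 (permutation p = 0.323), and r was 0.125 without chromosomes 19 and 17, so the relation rested on those.

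Part of chromosome 17 held several named losses near each other. SPOP (49598884 to 49678163, 2 lost regions), DLX4 (49968572 to 49974959, 1 lost region at a gene end) and PDK2 (50094737 to 50112152, 4 lost regions) lie in sequence. COL1A1 (50184101 to 50201631), the next of the named genes, had 2.33 ± 0.577 peaks in control and 5 ± 1 in HMGA2 libraries (SD, n = 3; log2 change 0.85, limma adjusted p = 0.0838). At FAM120B a peak at a gene end was lost, with no lost region there, while the locus held 4 peaks in every HMGA2 and 2 in every control library.

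The first pattern weighed was the higher number of peaks with HMGA2. Deeper sequencing as the whole cause was weighed with summit pileups thinned to equal background. The ratio was then 1.26 and above 1 in each donor (1.29, 1.28 and 1.21). Only summits of peaks already called were thinned, and peaks were not called anew. In HMGA2 donor 1 few peaks were removed (434738 before, 424309 after). This argues against a surplus of summits that only depth lifts over the common minimum pileup of 7, and leaves other effects of depth open. Weaker enrichment of the same sites over background stays open. Peaks with a fold of at least 10 numbered about the same (ratio 0.989), which does not separate it from added weak sites. The lowest fold among the 50000 highest peaks was 15.3 ± 0.843 in HMGA2 and 17.5 ± 0.710 in control libraries (SD, n = 3). It was lower with HMGA2 in each donor (exact permutation p = 0.1). That HMGA2 may open many sites weakly also stays open, since a peak list does not separate the 2.

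The second pattern was the set of regions gained and lost in all donors. Weaker enrichment of sites that stay accessible remains open. Only 4 regions were among the 50000 highest peaks of all 3 HMGA2 libraries without any deposited control peak, and 1 in the opposite direction. These counts do not decide it. The weakest deposited peak of each list had a −log10 p of only 2.21 to 2.53, so graded changes of any kind would leave few such regions. A candidate biological explanation is that HMGA2 shifts accessibility between sites by degrees, which these lists do not test apart from such weakening.

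The third pattern was the higher peak number in the list of neuronal and synaptic genes. Gene length stays open, since the median of the list lay at percentile 95.5 of 10000 lists matched on length, inside their middle 95% (−0.08 to 0.25), although over all tested loci the change showed little rank relation with length (Spearman's rho −0.0206). Low gene density also stays open, since gained regions had a median of 5 genes within 500 kb, against 7 around shared and 8 around lost regions, in each donor 5 against 7 and 7. By the criterion written beforehand, evenly spread background taken as peaks stays open. The median of 5 genes lay within 1 gene of the 4 around random positions. Gains of each donor placed at random coincided in all 3 donors at most 9 times in 20 draws, where 6663 did. Random placement gives almost no coincidence in any case, so this argues only against background at unrelated positions in each donor. Background that recurs at the same positions was not tested.

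The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Gained regions (6663) and lost regions (5244) were as numerous in 1 split of 10, the real one, with at most 776 in the others. Loci with more peaks (372) and with fewer (594) were also as numerous in 1 of 10, with at most 66 in the others, and as many gene lists passed in 3 of 10. Other splits that part the libraries of every donor, as the real one does, gave at most 205 regions and 29 loci.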
